A study of Caenorhabditis elegans with 79 samples.

How the data were processed

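Processed tables deposited with the series were used, and no reads were realigned. Per the submitters' processing notes, small RNA values were made with DESeq2 (version not stated), mRNA with Trimmomatic 0.35 and TopHat2 (version not stated), and chromatin reads were aligned with Bowtie 0.12.7. Genome build, annotation and read filters are not given in the sources used here. The mRNA table deposited by the authors is named as normalized counts, but its values are not whole, their lowest nonzero values fall as gene length grows and they were read as FPKM. It held 21976 genes, 21954 with an identifier, of which 19434 matched the supplied gene table. The small RNA table deposited by the authors holds a normalized signal, reads per feature divided by 1 size factor per library, for 2434 features, among them 191 transposon identifiers, 198 without an identifier and 52 with values identical to another feature. The chromatin table deposited by the authors gives FPKM in regions of 1000 bp. Chromosome names were taken from the RefSeq genes of assembly WBcel235, which was used for nothing else. For the separate F5 experiment, 12 columns could not be matched to a sample label, and their libraries were not used.

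Read depth was recovered where values were whole multiples of a step. For small RNA all values of each library were whole within 0.02 reads, giving the read count of each library, 54599 to 2274591. The deposited columns of 2 morc-1 late small RNA libraries carry the same header, so their replicate numbers are unknown. They were left out of the fit with the replicate number as a block. For chromatin 87.5 to 92.1% of H3K9me3 values and 83.3 to 87.9% of H3K36me3 values were whole within 0.1, giving the fragment totals of the report, although a step 2 times as large or as small is not excluded. Input and mRNA depth could not be recovered.

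Libraries were grouped by strain and stage. RNA values were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with group means, moderated variance with a trend and Benjamini-Hochberg adjusted p under 0.05, for genes with a mean of at least 10 over all libraries of an assay (7324 for mRNA, 2349 for small RNA). Among the mRNA genes tested, 103 held a 0 in some library and 63 had a group at 0. Comparisons were each mutant against WT early and late, late against early in each strain, and the interaction of generation with each mutant. For chromatin the same model was fitted per mark on log2(FPKM + 1) over 100250 regions with a mean input of at least 2 FPKM, without division by input. The plan had been to fit 14 H3K9me3 libraries together, and 8 were used because the F5 columns were unmatched. Groups with 1 library borrow the spread of the others in fits that compare them with replicated groups, and comparisons of 1 library with 1 were given without a test. The hrde-1-dependent regions had at least 20 FPKM in WT late, a log2 fall of at least 1 in each of the 2 hrde-1 late libraries, with no limma call required; neighbouring regions were joined into runs.

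There were 25 gene lists fixed in advance, tested with camera (preset correlation 0.01, and again with an estimated correlation) where at least 3 members were measured, with p adjusted over lists within a comparison. Region sets were tested with camera, with p not adjusted over sets, and set against 10000 random sets matched on mean level. Overlaps were set against the product of both counts over the features tested and against 100 simulated data sets of unchanged groups that shared the WT libraries. Fisher's exact test compared small RNA calls of genes whose mRNA rose with those of other genes. Genes were named by a rule written in advance: for each late mutant comparison the mutated genes, the 10 largest rises and 10 largest falls among calls whose libraries did not overlap, and up to 4 called members per list; for other comparisons the 3 largest each way. The 10 longest runs and the 5 largest H3K36me3 changes each way in morc-1 late were named likewise. Named after their values were seen were the further 16 of the 26 rises in morc-1 late, list members in late against early comparisons, the genes with both assays and the input blocks. Input was called unequal where a block differed from WT by at least 0.6 on the log2 scale.

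The methods were tested on simulated data built from the deposited values with log2 changes of 1, 2 and 3. For morc-1 late against WT late, limma recovered 10.3, 71.2 and 93.9% of changed mRNA genes, with 5.69% false calls, and 57.4, 81.8 and 89.4% of small RNA features, with 4.40%. It recovered 45.6, 92.4 and 97.0% of H3K9me3 regions (4.88%) and 77.9, 100 and 100% of H3K36me3 regions (1.60%). edgeR 4.0.16 recovered 50, 93.9 and 100% of small RNA features (3.57%) and DESeq2 1.42.0 51.5, 92.4 and 100% (4.14%). A mRNA change of 1 on the log2 scale was thus mostly not detectable with 2 libraries per group. Replicates correlated at r = 0.897 to 0.950 across mRNA genes and 0.859 to 0.993 across small RNA features.

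Alternatives were pseudocounts of 0.5 and 5 (0.25 and 5 for chromatin), no filter, quantile normalization, only the compared groups in the fit, the replicate number or the library series as a block, leaving out each library in turn, edgeR quasi-likelihood and DESeq2 on recovered small RNA reads, the ratio to input, a log2 drop of 2, at least 40 FPKM in WT late, and regions defined from the early libraries. Chosen after seeing the data were leaving out the shallowest small RNA library, taking identical features once, a block within each generation (centred, so that stages are compared by group means), leaving out genes with a 0 or the late mRNA libraries numbered 2, the authors' GRH and GRTS regions, and leaving out regions of unequal input or marked misannotated by the authors. Genes overlapping the regions were not analysed here, because no annotation stated to be of the files' build was available. Random steps used seed 1, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.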

Results

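The series covered 79 sequencing libraries of Caenorhabditis elegans: 12 of polyadenylated mRNA, 16 of small RNA, 8 of chromatin immunoprecipitated for H3K9me3, 19 for H3K36me3, 12 inputs, and a separate F5 experiment of 6 H3K9me3 libraries with 6 inputs that was not analysed here. The strains were wild type (WT), morc-1, hrde-1 and, for chromatin, met-1, met-1 morc-1 and met-1 hrde-1. By the labels, animals came from a lower temperature, were grown at 25 °C and were collected early (generation 1) or late (generation 4 or 5). hrde-1 encodes a nuclear Argonaute, morc-1 a GHKL ATPase and met-1 an H3K36 methyltransferase. The mRNA groups held 2 libraries each, and their FPKM sums ran from 0.963 to 1.404 M with unknown read depth. The small RNA groups held 3 WT, 3 morc-1 and 2 hrde-1 libraries per stage, with 54599 to 2274591 recovered reads. The H3K9me3 groups held 1 library, apart from 2 each for morc-1 late and hrde-1 late, at 9.02 to 17.3 M fragments. Their WT late library was of generation 4, whereas morc-1 late and hrde-1 late each held 1 library of generation 4 and 1 of generation 5. The H3K36me3 groups held 1 early library per strain, 3 WT late libraries and 2 late libraries per mutant, at 9.24 to 13.95 M fragments. All p-values measure only the spread between these libraries, since the labels do not say that replicates came from separate cultures.

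Among the mutated genes, morc-1 mRNA was 54.5 ± 0.548 FPKM in WT early (SD, n = 2) and 13.9 ± 0.324 in morc-1 early, and 30.2 ± 8.39 in WT late and 10.9 ± 1.58 in morc-1 late. Its log2 change was -1.90 ± 0.30 (SE) early (limma adjusted p = 0.078) and -1.37 late (adjusted p = 0.142), so neither passed; late it passed with a replicate block within each generation. In hrde-1 mutants morc-1 mRNA stood at 49.5 ± 1.84 FPKM early and 29.6 ± 10.2 late. The hrde-1 gene, listed as wago-9, was at 216 ± 25.4 FPKM in WT early, 143.1 ± 24.9 in morc-1 early and 142.7 ± 12.34 in hrde-1 early. Late it was at 99.7 ± 3.50 in WT, 175 ± 0.648 in morc-1 and 74.8 ± 8.92 in hrde-1. The hrde-1 mutant did not pass against WT at either stage (log2 -0.59, limma adjusted p = 1, and -0.41, limma adjusted p = 0.530), and the labels name the alleles without stating which sequence they remove. met-1 mRNA was at 25.0 ± 3.06 FPKM in WT early and 10.0 ± 7.57 in WT late, and no met-1 strain was in the mRNA experiment. None of the 3 genes was among the small RNA features tested.

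To ask which genes depend on morc-1 after several generations at 25 °C, morc-1 late was compared with WT late. A set of 26 of 7324 genes rose and 0 fell, whereas a replicate block within each generation, chosen after seeing the data, gave 921 rises and 200 falls. F55B11.6 rose from 0.805 ± 0.471 to 59.6 ± 3.87 FPKM (SD, n = 2), a log2 change of 5.09 ± 0.34 (limma adjusted p = 8.67e-05). rnh-1.3, an RNase H family gene, rose from 10.2 ± 1.64 to 208 ± 16.6 FPKM (log2 4.23 ± 0.25, adjusted p = 4.14e-05). timm-17B.2, a mitochondrial import translocase gene, rose from 34.8 ± 4.21 to 460 ± 39.8 FPKM (log2 3.69 ± 0.21). F40D4.13 rose from 1.13 ± 0.362 to 29.1 ± 0.800 FPKM and Y23H5A.8 from 1.01 ± 0.118 to 15.9 ± 0.339 FPKM. C38D9.2, a known nuclear RNAi target, rose from 0.466 ± 0.575 to 13.9 ± 2.90 FPKM (log2 3.39 ± 0.40, limma adjusted p = 0.00531). C56A3.9 was listed at 0 in both WT late libraries and at 85.3 and 50.96 FPKM in the morc-1 late libraries, although WT early held 47.03 and 17.6 FPKM. R09F10.3 (2.91), glit-1, a gliotactin homologue (2.87), F28F8.7 (2.67), F58H7.5 (2.67), ife-5, an eIF4E gene (2.51), C18D4.6 (2.48), usp-33 (2.42), fbxb-97 (2.36), C27C12.1 (2.27), csb-1 (2.25) and ceh-39, a homeobox gene (2.24), also rose on the log2 scale. So did K09E9.3, R07E4.5, T20F7.1, pqn-65, H40L08.1, saeg-2, Y34B4A.11 and pkhm-2, down to 1.797 for pkhm-2.

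**Figure D1:**
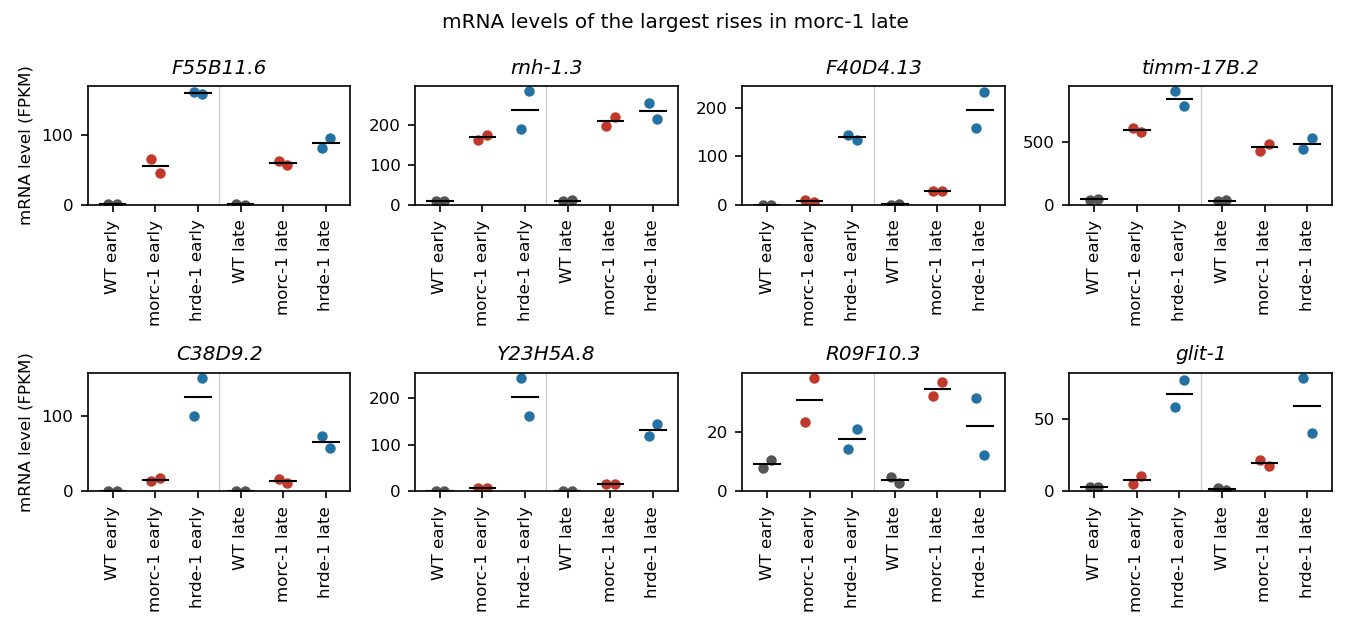
FPKM (y axis) of 8 genes that rose in morc-1 late, in the 6 mRNA groups (x axis); points are single libraries and bars are group means. rnh-1.3 stood at 10.2 FPKM in WT at both stages and at 168 to 236 FPKM in the mutants.

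Among gene lists fixed before the data were examined, only the known nuclear RNAi targets had a member that passed in morc-1 late. Of 5 known nuclear RNAi targets measured, 1 rose (2 adjusted over the list alone), 0 fell and 4 did not pass. Their median log2 change was 1.18 (camera adjusted p = 0.00970, and adjusted p = 0.367 with an estimated correlation), and quantile normalization removed the call (adjusted p = 0.139). All 23 P granule genes were higher with a median of 0.76, although 0 passed (8 adjusted over the list alone), and 20 of 22 oogenesis genes were higher (median 0.79; 0 passed, 9 adjusted over the list alone). The intestine list (16 genes, median -0.65), muscle list (13, -0.57) and neuron list (6, -0.36) were lower, with 0 members passing. Factors of H3K9 methylation (12 genes, 0.91), of H3K36 and H3K4 methylation (11, 0.87) and of small RNA amplification (20, 0.69) were higher, and 17 histone genes were lower (-0.26), again with 0 passing. These camera calls ran from adjusted p = 2.66e-07 for intestine to 0.00796 for histones, and with an estimated correlation none passed (lowest adjusted p = 0.102). The 21 major sperm protein genes changed sign under quantile normalization, from 0.44 to -0.32. Fold changes are on the log2(value + 1) scale throughout, for all assays. limma gave unadjusted p below 0.05 for 713 higher and 239 lower genes, the median of all genes was shifted by 0.245, and quantile normalization gave 35 rises and 6 falls. Leaving out any of 4 single libraries cut the 26 calls, to 7 without morc-1 late replicate 1, 8 without morc-1 late replicate 2, 14 without WT late replicate 1 and 15 without WT late replicate 2.

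Early, morc-1 raised 8 genes and lowered 0 (17 and 1 with a replicate block within each generation), and all 8 also rose late. F55B11.6 went from 1.36 ± 0.903 to 55.2 ± 14.2 FPKM (log2 4.60 ± 0.34, limma adjusted p = 2.28e-04). rnh-1.3 went from 10.2 ± 0.656 to 168 ± 9.89 FPKM (3.92 ± 0.25) and C38D9.2 from 0.220 ± 0.146 to 15.4 ± 2.56 FPKM (3.75 ± 0.40). The 5 known nuclear RNAi targets were higher with a median of 1.03 (1 rose, 2 adjusted over the list alone), and this camera call also passed with an estimated correlation (adjusted p = 0.0437). P granule genes (23, median -0.45), oogenesis genes (22, -0.54) and Argonautes (14, -0.40) were lower, and major sperm proteins (21, 0.87) and spermatogenesis genes (15, 0.81) were higher. Of these lists 0 members passed (5 oogenesis genes adjusted over the list alone), and the camera calls were lost with an estimated correlation (adjusted p = 0.177 to 0.572). P granule and oogenesis genes thus stood lower early and higher late in morc-1 relative to WT. limma gave unadjusted p below 0.05 for 91 higher and 130 lower genes, and without morc-1 early replicate 1 the 8 rises became 5.

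The hrde-1 mutant, compared with WT as the reference for nuclear RNAi loss, had 41 rises and 3 falls early (68 and 10 with a replicate block within each generation). C38D9.2 rose from 0.220 ± 0.146 to 125 ± 35.3 FPKM (log2 6.67 ± 0.40, limma adjusted p = 1.38e-05), F40D4.13 from 0.483 ± 0.198 to 139.1 ± 8.27 FPKM (6.57 ± 0.33) and F58H7.5 from 0.699 ± 0.521 to 138.9 ± 15.6 FPKM (6.39 ± 0.42). R10E4.1 fell from 26.8 ± 0.282 to 5.63 ± 0.0196 FPKM and C33B4.4 from 31.3 ± 4.63 to 6.99 ± 0.728 FPKM. nola-3, a small nucleolar RNP gene, was listed at 0 in both hrde-1 early libraries against 26.8 and 14.1 FPKM in WT early. Of the 5 known nuclear RNAi targets 2 rose (4 adjusted over the list alone), C38D9.2 and F15D4.5, with a list median of 1.93 (camera adjusted p = 4.53e-21, and 0.00555 with an estimated correlation). Major sperm proteins (median 1.04) and spermatogenesis genes (0.97) were higher with 0 passing, and with an estimated correlation camera gave adjusted p = 0.976 for both. Of the 41 rises 40 also rose late, and 1 of the 3 falls also fell late.

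Late, hrde-1 had 188 rises and 50 falls (494 and 216 with a replicate block within each generation). F40D4.13 rose to 195.5 ± 53.1 FPKM (log2 6.51 ± 0.33, limma adjusted p = 5.50e-06), Y23H5A.8 to 132 ± 17.5 FPKM (6.04 ± 0.31), F47B7.6 from 0.260 ± 0.368 to 101.3 ± 72.3 FPKM (6.17 ± 0.56) and C38D9.2 to 65.7 ± 11.2 FPKM (5.56 ± 0.40). The F-box gene fbxa-33 was listed at 0 in WT late and at 130.7 and 128.9 FPKM in hrde-1 late. R09H3.2, listed at 0 in WT late and at 749.5 and 999 FPKM in hrde-1 late, Y38H6C.7 (0 against 89.2 and 109.5 FPKM), Y43F4A.3 (0 against 54.6 and 74.1), T11F9.19 (0 against 55.7 and 121), Y54H5A.5 (0 against 197 and 272) and C56A3.9 (0 against 53.2 and 97.8) were the other rises named by size. Among the falls, the heat shock genes hsp-70 (32.9 ± 0.651 to 1.46 ± 1.20 FPKM, log2 -3.88 ± 0.57), hsp-16.41 (-3.71), hsp-16.2 (-3.57) and hsp-12.3 (-2.27) were 4 of 6 measured list members. The cuticle genes cut-3 (-4.29) and dpy-14 (-3.93) fell, as did mtre-1 (-4.05 ± 0.39), C27A7.8 (-3.89), R09H10.7 (-3.88) and F15B9.8 (-3.67). The yolk protein gene vit-5 was listed at 0 in both hrde-1 late libraries against 8781 and 2067 FPKM in WT late, and C03C10.9 at 0 against 66.9 and 64.4 FPKM.

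By list, hrde-1 late raised 3 of 5 known nuclear RNAi targets (3 adjusted over the list alone; median 2.13), C38D9.2, F15D4.5 (4.08 ± 3.13 to 136 ± 9.62 FPKM, log2 4.90 ± 0.49) and R03D7.2 (2.13 ± 0.43). Of 21 major sperm proteins 3 rose (21 adjusted over the list alone; median 3.17), msp-142 (3.72 ± 0.73), msp-49 (3.68) and msp-57 (3.07). Of 15 spermatogenesis genes 5 rose (14 adjusted over the list alone; median 3.20), among them msd-4 (3.55), nspd-1 (3.48), gsp-4, a sperm phosphatase (3.26) and ssp-16 (3.01). Of 23 P granule genes meg-4 (2.51), meg-1 (1.70) and meg-3 (1.51) rose, and of 22 oogenesis genes perm-4 (1.65) rose. Of 16 intestine genes 3 fell (6 adjusted over the list alone; median -0.59), the cathepsin genes cpr-4 (-2.34) and cpr-5 (-2.15) and the intermediate filament gene ifb-2 (-1.29). The linker histone gene hil-7 fell (-3.44) with 0 other of 17 histone genes passing (3 adjusted over the list alone; median -0.36), and the lysozyme gene lys-7 rose (1.93). The 13 muscle genes were lower (-0.62) with 0 passing. Single libraries set the direction of some lists: as signed -log10 camera p, muscle and histones stood at 0.150 and 0.254 without hrde-1 late replicate 1 and at -11.7 and -9.48 without replicate 2, and oogenesis at -0.160 without WT late replicate 1. All of these list calls were lost with an estimated correlation in camera, from adjusted p = 0.0531 for heat shock and 0.0639 for nuclear RNAi targets and intestine to 0.816 for oogenesis. Quantile normalization gave 186 rises, 63.9% of its calls against 78.99%, and without hrde-1 late replicate 2 the 238 calls became 115.

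All 26 genes that rose in morc-1 late also rose in hrde-1 late, where 0.667 would be shared by independent calls. Libraries simulated with the shared WT libraries and no mutant effect shared 0.02 on average and at most 1. Few calls arise at all without a mutant effect, so such counts do not measure what shared controls add between mutants with real calls. The 26 shared genes became 6 and 8 without morc-1 late replicates 1 and 2, 14 and 15 without WT late replicates 1 and 2, 15 with the replicate number as a block and 5 with only the compared groups in the fit. With a replicate block within each generation, 186 of the 921 rises and 64 of the 200 falls in morc-1 late were shared. Early, all 8 morc-1 rises were among the hrde-1 rises (0.0448 by independent calls, and 0.01 on average and at most 1 in simulation). Across genes the late changes of both mutants had a covariance of 0.265 against 0.109 in simulation, a difference of 0.157, and a correlation across genes, which are not independent replicates, of 0.526 against 0.500. Early the covariance was 0.113 against 0.108. Part of the excess over independence may come from the shared controls, which could not be split.

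WT itself differed between stages, with 229 rises and 293 falls late against early. F07H5.3a was listed at 0 in WT early and at 4681 and 4593 FPKM in WT late, and Y106G6D.5a (145 and 61.8 FPKM late) and Y51H4A.24 (107.5 and 49.6 FPKM late) were also listed at 0 early. The table holds no read counts, so whether a 0 in one group beside high values in another, throughout, reflects expression or the authors' quantification is open. The yolk protein genes vit-6 (11750 and 5919 FPKM early) and vit-2 (7509 and 4413 FPKM early) and H16D19.4 (44.6 and 70.4 FPKM early) were listed at 0 late. Of 6 heat shock genes 4 rose (4 adjusted over the list alone; median 3.79), hsp-16.2 (log2 5.53), hsp-16.41 (5.12), hsp-70 (4.57) and hsp-12.3 (3.00). Of 16 intestine genes 6 rose and 1 fell (12 and 1 adjusted over the list alone; median 1.17), with mtl-1, a metallothionein (4.82), cpr-4 (3.01), cpr-1 (3.00) and spp-1 (2.51) up and the peptide transporter pept-1 (-1.54) down. Both of these lists passed with an estimated correlation (camera adjusted p = 0.0129 each). Of 23 P granule genes 9 fell (18 adjusted over the list alone; median -0.97), such as meg-1 (-2.21), meg-3 (-1.86) and oma-1 (-1.42), and of 22 oogenesis genes 7 fell (14 adjusted over the list alone; -0.96), such as spn-4 (-1.59), chs-1, a chitin synthase (-1.36), and puf-5 (-1.30). Of 12 H3K9 methylation factors 3 fell (11 adjusted over the list alone; -1.34), the methyltransferase genes set-25 (-1.75) and met-2 (-1.40) and arle-14 (-1.15), and of 14 Argonautes hrde-1 (-1.10), wago-1 (-1.0) and alg-5 (-1.19) fell. Muscle genes (13, 0.96; 2 rose, tni-3 and unc-54), neuron genes (6, 0.53; sbt-1 rose) and histones (17, 0.63; 5 rose) were higher. With an estimated correlation the camera calls of these and of the lower lists were lost, with adjusted p = 0.114 for neuron genes, 0.240 for histones, 0.328 for P granule and muscle genes and 0.565 for oogenesis genes, H3K9 factors and Argonautes.

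The number of these stage calls, and the direction of some lists, rested on few libraries and on scaling. The median of all genes was shifted by -0.587, and quantile normalization gave 534 rises and 265 falls, 66.8% upward against 43.9%. The 522 calls became 43 without WT early replicate 1, 28 without WT early replicate 2, 1053 without WT late replicate 1 and 339 without WT late replicate 2. Major sperm proteins and spermatogenesis genes turned to 0.27 and 0.20 under quantile normalization, and the known nuclear RNAi targets also changed sign. For the 5 nuclear RNAi targets the median (-0.22) and mean (-0.33) were negative while camera placed the list upward (camera adjusted p = 0.747). The lower germline and higher somatic lists in WT late bear on every late comparison with WT, including the higher P granule and oogenesis lists in morc-1 late.

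In morc-1, late against early gave 21 rises and 7 falls. hsp-16.2 (log2 5.76 ± 0.70), hsp-70 (5.44) and hsp-16.41 (5.37) were 3 of 6 heat shock genes that rose (4 adjusted over the list alone; median 3.66; camera adjusted p = 0.00873 with an estimated correlation), and mtl-1 (4.51) and cpr-4 (1.74) were 2 of 16 intestine genes that rose. F07H5.3a was listed at 0 early and at 2460 and 3268 FPKM late, and Y106G6D.5a at 0 early and at 123.9 and 72.9 FPKM late. vit-6 (10860 and 6041 FPKM early) and vit-2 (7293 and 4473 FPKM early), the 2 of 6 yolk genes called lower, and C53C7.5a (9.84 and 39.6 FPKM early) were listed at 0 late, with the same doubt about the 0; without genes that hold a 0 in any library the 28 calls became 12. The median of all genes was shifted by -0.225. The 28 calls became 14 without morc-1 early replicate 1, 12 without morc-1 early replicate 2, 13 without morc-1 late replicate 1 and 12 without morc-1 late replicate 2. For the interaction of generation and morc-1, limma called 0 genes in either direction (unadjusted p below 0.05 for 709 higher and 173 lower), whereas a replicate block within each generation gave 544 higher and 76 lower. P granule (median 1.11; 0 passed, 13 adjusted over the list alone) and oogenesis genes (1.396; 0 passed, 14 adjusted over the list alone) were higher in it, without passing camera with an estimated correlation (adjusted p = 0.174 and 0.293). Without WT late replicate 1, or without morc-1 early replicate 2, it held 1 call.

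In hrde-1, late against early gave 56 rises and 13 falls. F07H5.3a rose by 8.90 on the log2 scale, Y54H5A.5 was listed at 0 early and at 197 and 272 FPKM late, and fbxa-33 at 0 early and at 130.7 and 128.9 FPKM late. vit-6 (10691 and 8619 FPKM early), vit-2 (6714 and 5976) and vit-5 (3224 and 2661) were listed at 0 late, so the 3 of 6 yolk genes called lower all rest on a 0 that may come from the authors' quantification. Major sperm proteins (median 1.67) and spermatogenesis genes (1.69) were higher with 0 passing (camera adjusted p = 1.85e-10 and 1.86e-08, and 0.421 and 0.275 with an estimated correlation). The median of all genes was shifted by -0.453, and quantile normalization gave 265 rises and 69 falls. The 69 calls became 22 without hrde-1 early replicate 1, 26 without hrde-1 early replicate 2, 2062 without hrde-1 late replicate 1 and 24 without hrde-1 late replicate 2. In the interaction of generation and hrde-1, 3 genes were lower: mtre-1 (-4.17 ± 0.55, limma adjusted p = 0.0442), F07H5.3a (-3.28) and vit-5, listed at 0 in hrde-1 late only. The calls of F07H5.3a and vit-5 rest on groups listed at 0, and without genes that hold a 0 in any library 1 call was left; a replicate block within each generation gave 3 higher and 5 lower. The 6 heat shock genes were lower in it (median -2.49; 4 adjusted over the list alone; camera adjusted p = 0.0332 with an estimated correlation). It held 1 call without WT early replicate 1, without WT early replicate 2 or without hrde-1 early replicate 1, and 26 without WT late replicate 2.

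Expression also differed between the X chromosome and the autosomes (658 and 6605 genes). In WT, X-linked genes changed by a median of -0.04 late against early while autosomal genes changed by -0.63, a difference of 0.592. The difference was 0.296 in morc-1 and 0.666 in hrde-1. Relative to WT late, the X chromosome of morc-1 late stood 0.316 lower than the autosomes (-0.316), whereas in hrde-1 late it stood 0.077 higher. In single libraries X minus autosomes was -0.336 and -0.318 in WT late and -0.600 and -0.452 in morc-1 late. It was -0.386 and -0.0917 in hrde-1 late, so the higher value there rests on replicate 2 alone. The somatic minus germline level was also lower in both morc-1 late libraries (-0.323 and 0.2498) than in WT late (0.887 and 1.45), and whether this accounts for the X chromosome was not tested. Of X-linked genes 12 (1.82%) rose in morc-1 late against 13 autosomal genes (0.197%), and in hrde-1 late 45 (6.84%) rose against 2.15% of autosomal genes. No test was run on this contrast, and genes of a chromosome are not independent.

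Small RNAs, measured as normalised reads per gene or transposon feature, changed widely in morc-1 late, where 464 of 2349 features rose and 597 fell. C46G7.3 rose from 8.80 ± 6.87 to 2404 ± 848 reads (SD, n = 3), a log2 change of 8.30 ± 0.58 (limma adjusted p = 3.75e-07). The cadherin gene cdh-5 rose from 28.2 ± 18.7 to 496 ± 72.2 reads (4.39 ± 0.70), AH9.1 from 50.6 ± 20.7 to 664 ± 132 and the collagen gene col-157 from 297.5 ± 46.1 to 2645 ± 673 (3.13 ± 0.23). F18G5.6 (3.50), Y53F4B.43 (3.42), bbln-1 (3.34), Y16B4A.2 (3.02), K09E3.1 (3.02) and col-154 (2.94) also rose. abhd-14 fell from 760 ± 247 to 2.17 ± 0.183 reads (-7.85 ± 0.49), the cadherin gene cdh-1 from 3322 ± 1195 to 34.7 ± 13.4 (-6.56 ± 0.49) and the axin gene pry-1 from 912 ± 268 to 24.1 ± 10.8 (-5.23 ± 0.39). W05H12.1 (-6.50), F13A7.11 (-6.27), T28D6.4 (-6.02), C15C6.1 (-5.94), the serotonin receptor gene ser-5 (-5.41), Y39B6A.9 (-5.29) and Y41C4A.12 (-5.08) fell as well. Of 11 known nuclear RNAi target features 4 rose and 4 fell (the same adjusted over the list alone), with R06C1.4 (-3.60), F07B7.2 (-1.42, in 2 features with identical values) and bath-45 (-0.90) the falls. After quantile normalization 1 rose and 4 fell, so the number of rises depended on scaling. The list median was -0.49 while camera placed the list upward (camera adjusted p = 0.945). Of 13 histone features his-24 rose (1.03) and hil-3 (-2.26), hil-8 (-1.73) and his-67 (-0.81) fell. The immune regulator gene pals-22 (-3.42) and the heterochromatin gene hpl-1 (-1.64) fell, and pek-1 (0.85) and Y7A5A.3 (0.67), an ERGO-1 class target, rose.

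Scaling set the balance of these small RNA calls. The median of all features was shifted by -0.335 in morc-1 late, and quantile normalization gave 599 rises and 442 falls, under which the histone list changed sign. For 2 morc-1 late libraries the replicate number could not be told, since their deposited columns carry 1 header. Without one of them the 1061 calls became 701, and without the other 1038. Early, morc-1 changed 372 features, 27.2% of them upward and 271 downward (444 rises and 263 falls after quantile normalization; median of all features -0.178). C46G7.3 (log2 5.52 ± 0.58), cdh-5 (4.14) and F18G5.6 (2.503) rose, and W05H12.1 (-6.56 ± 0.63), the F-box gene fbxa-184 (-6.23) and kal-1, the anosmin gene (-5.36), fell. Of these, 89 rises and 235 of the 271 falls recurred late. morc-1 early replicate 1 was the shallowest library, with 54599 recovered reads and 244 tested features at 0.

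In hrde-1, small RNAs fell at more features, with 300 rises and 986 falls early and 431 rises and 1246 falls late. By their labels all hrde-1 small RNA libraries were numbered after those of WT and morc-1, so library series cannot be told apart from strain here. The hrde-1 late libraries were of generation 4 only, whereas WT late held generations 4 and 5. Early, trp-4, a TRP channel gene, fell from 1900 ± 487.5 to 9.74 ± 3.67 reads (log2 -7.48 ± 0.33, limma adjusted p = 1.54e-09), abhd-14 by 7.38 and T28D6.4 by 7.16, while C46G7.3 (4.82), best-25 (4.23) and T04A11.14 (3.96) rose. Late, cdh-12 fell from 6016 ± 1493 to 20.2 ± 1.13 reads (-8.12 ± 0.55), abhd-14 by 8.14, cdh-1 by 7.92, trp-4 by 7.67, ser-5 by 7.60, C15C6.1 by 7.58, W03F11.5 by 7.52, T27F6.8 by 7.51, Y105E8A.1 by 7.50 and F13A7.11 by 7.42. F21D9.7 rose from 79.7 ± 3.17 to 6282 ± 334 reads (6.28 ± 0.27), and C46G7.3 (8.45), T04A11.14 (5.50), T24H5.1 (4.72), F07C7.1 (4.44), epic-2 (4.39), Y53F4B.43 (4.31), T23B12.9 (4.196), F20B6.5 (3.97) and Y43F4A.1 (3.93) rose. Of the 11 known nuclear RNAi target features 8 fell at each stage (8 adjusted over the list alone) and 0 rose, with late changes of -4.53 for F07B7.1, -3.91 for R06C1.4, -3.72 for F15D4.5 (6454 ± 612 to 489 ± 26.4 reads) and -3.59 for eri-6. Early the list had a median of -2.39 (camera adjusted p = 0.0222, and 0.322 with an estimated correlation), and late -2.44 (adjusted p = 0.158). Late, the histone features hil-3 (-4.86) and his-24 (-3.16) fell and his-50 (2.69) rose, pals-22 (-5.55) and pals-25 (-2.65) fell, spe-41 (-2.86) and fer-1 (-1.71) fell and spe-47 (0.62) rose. The ERGO-1 class features E01G4.5 (-4.70), fbxb-37 (-3.11) and E01G4.7 (-1.83) fell and Y7A5A.3 (1.60) rose; smut-1 (-1.61) fell and rde-11 (1.07) and zim-1 (0.35) rose. hpl-1 (-1.60) and cec-4 (-1.28) fell in the deposited scaling but stood at 0.0398 and 0.275 after quantile normalization. The median of all features was shifted by -0.712 early and -1.08 late, and quantile normalization gave 793 rises and 496 falls early and 840 and 684 late. Without hrde-1 early replicate 1 the 1286 early calls became 820, and without replicate 2 they became 808.

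Late, 282 features rose and 543 fell in both mutants, against 85.1 and 317 by independent calls and 0 in simulation, while 71 moved in opposite directions. The covariance of both late changes was 1.64 against 0.100 in simulation (difference 1.54), and the correlation across features was 0.693 against 0.452. Early, 50 rose and 229 fell in both (12.9 and 114 by independent calls), 35 moved in opposite directions, and the covariance was 0.762 against 0.0984. Part of the excess over independence may again come from the shared controls. The simulated count, with no mutant effect and so few calls, does not measure that part. No small RNA list passed camera with an estimated correlation.

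Between stages, small RNAs changed little in WT, with 2 rises and 10 falls. nlp-40, a neuropeptide gene, rose from 114 ± 21.3 to 340 ± 48.6 reads (log2 1.57 ± 0.20, limma adjusted p = 0.00343) and T20F7.5 rose (1.12), whereas C46G7.3 (-3.84), H04D03.4 (-3.07) and F21D9.7 (-1.78) fell. edgeR and DESeq2 on recovered reads called 34 and 58 features, quantile normalization gave 7 rises and 21 falls, and the 12 calls became 7 without WT early replicate 1, 3 without WT early replicate 3, 4 without WT late replicate 1, 24 without replicate 2 and 5 without replicate 3. In morc-1, 42 features rose and 204 fell (33.7% upward after quantile normalization against 17.1%, and 205 rises and 192 falls by DESeq2), with Y41C4A.12 (-3.74), abhd-14 (-3.68) and F13A7.11 (-3.20) falling and Y53F4B.43 (1.64), F53G2.3 (1.60) and fbxa-10 (1.60) rising. These 246 calls became 390 without morc-1 early replicate 2 and 136 without 1 of the morc-1 late libraries of unknown number, and nearly as few without morc-1 late replicate 1. In hrde-1, 290 rose and 459 fell (222 and 270 after quantile normalization; median of all features -0.207), with lido-13 (3.73), taf-3 (3.57) and fbxa-149 (3.06) rising and Y41C4A.12 (-4.63), F13H10.5 (-4.38) and dmsr-3 (-4.27) falling. Each hrde-1 library left out reduced the 749 calls, to 338 and 322 for early replicates 1 and 2 and 358 and 346 for late replicates 1 and 2. The 16 ERGO-1 class features were higher late in WT (median 0.44) and in hrde-1 (0.72, 2 rose and 0 adjusted over the list alone), with camera adjusted p of 0.0467 and 0.0182, and 0.536 and 0.676 with an estimated correlation.

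In the interaction of generation and morc-1, 15 features were higher and 27 lower (23 and 21 after quantile normalization). H04D03.4 (log2 2.13 ± 0.34, limma adjusted p = 0.00971), K06C4.14 (2.09) and F07B7.6 (1.92) were higher, and Y41C4A.12 (-3.56 ± 0.46), abhd-14 (-3.49) and Y61A9LA.5 (-3.07) were lower. Libraries taken out singly moved the 42 calls to between 11, without WT early replicate 1, and 84, without morc-1 early replicate 2. In the interaction with hrde-1, 243 features were higher and 235 lower (41.4% upward after quantile normalization against 50.8%), among them Y73B3A.7 (3.65), C46G7.3 (3.63) and F21D9.7 (3.58) upward and Y41C4A.12 (-4.45), dmsr-3 (-4.39) and F13H10.5 (-4.195) downward. These 478 calls became 120 without hrde-1 early replicate 1 and fewer without replicate 2, 162 and 135 without hrde-1 late replicates 1 and 2, 216 and 261 without WT early replicates 1 and 3, and 224 and 277 without WT late replicates 1 and 3.

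Genes whose mRNA rose were compared with their small RNAs over 659 genes tested in both assays. Of 20 such genes that rose in morc-1 late, 12 had fewer small RNAs, 4 more and 4 no call, with a median log2 small RNA change of -1.09. The share with fewer was 60% against 27.1% of the other genes (Fisher's exact test, two-sided, p = 0.00364). Small RNAs fell at rnh-1.3 (-4.05), F55B11.6 (-2.69), F40D4.13 (-1.48), Y23H5A.8 (-1.39) and timm-17B.2 (-1.31), and rose at saeg-2 (0.99), F58H7.5 (0.82), pkhm-2 (0.67) and C38D9.2 (0.64). In hrde-1, 32 of 35 genes that rose early (91.4% against 50.5%, exact p = 7.31e-07) and 49 of 61 that rose late (80.3% against 61.9%, exact p = 0.00484) had fewer small RNAs. In morc-1 early it was 3 of 6 (50% against 11.03%, exact p = 0.0220). The WT libraries were shared within each assay only, and genes are not independent replicates.

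H3K9me3, a mark of heterochromatin, was compared over 100250 regions of 1000 bp; coordinates are 1-based and the genome build is not given in the sources used here. In hrde-1 late, 1221 regions fell and 108 rose against WT late. Regions with at least 20 FPKM in WT late and a fall of at least 1 on the log2 scale in each of the 2 hrde-1 late libraries numbered 412, in 152 runs, with 90 on chromosome I, 61 on II, 19 on III, 70 on IV, 111 on V and 61 on X. The longest run, V 17638001 to 17651000, held 36.9 FPKM in WT late (1 library), 29.1 ± 2.30 in morc-1 late (SD, n = 2) and 10.1 ± 0.356 in hrde-1 late. The run at I 4460001 to 4469000 held 39.9, 26.1 ± 2.58 and 6.24 ± 1.21 FPKM, and X 225001 to 233000 held 26.3, 24.2 ± 5.30 and 5.53 ± 0.865 FPKM. II 12741001 to 12749000 went from 30.7 in WT late to 12.4 ± 0.254 FPKM in morc-1 late and 4.96 ± 0.694 in hrde-1 late, and I 2046001 to 2054000 from 26.4 to 8.79 ± 0.518 and 5.48 ± 1.34 FPKM. V 20295001 to 20305000 (56.1, 52.2 and 22.8 FPKM), I 11053001 to 11063000 (37.1, 27.9 and 13.9), IV 914001 to 922000 (41.98, 36.3 and 14.9), I 11066001 to 11074000 (34.8, 22.8 and 9.96) and IV 4127001 to 4134000 (38.5, 29.1 and 13.8) completed the 10 longest. Without hrde-1 late replicate 1 the 1329 calls became 834.

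**Figure D2:**
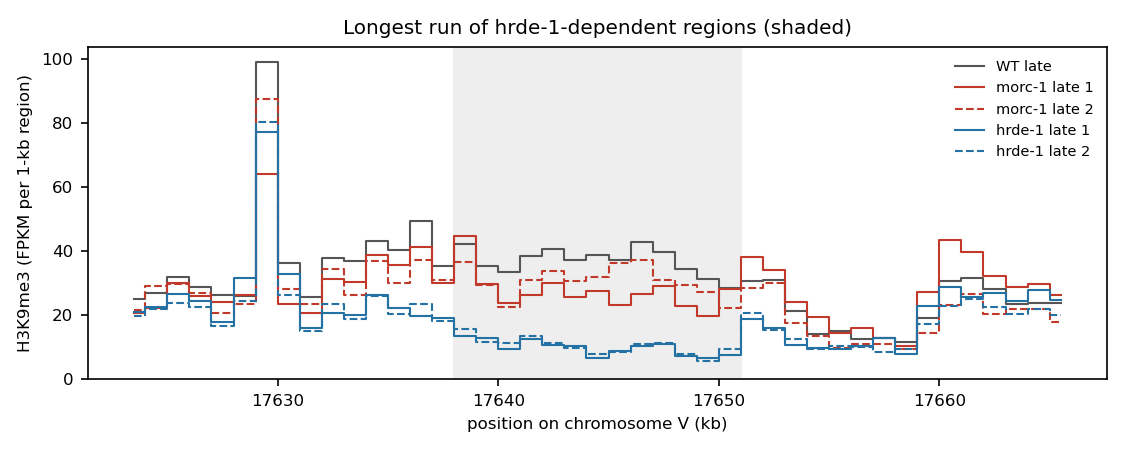
H3K9me3 (FPKM per 1-kb region, y axis) against position on chromosome V (kb, x axis) around the longest run of hrde-1-dependent regions, which is shaded; each line is a library. Within the run the mean was 36.9 FPKM in WT late and 10.1 FPKM in hrde-1 late.

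In morc-1 late, 366 regions fell and 225 rose, 214 of the rises in a block of chromosome V with raised morc-1 input (9 rises were left without regions of unequal input). Of the falls 341 were also falls in hrde-1 late, against 4.46 by independent calls and at most 1 in libraries simulated with the shared WT late library and no mutant effect. The simulated count is small because few calls arise without a mutant effect, and it does not measure what the shared library adds. Over all regions the covariance of both changes was 0.0456 against 0.0530 simulated. Most regions were called in neither mutant, so this covariance cannot decide whether a change was shared at few regions. Over the 412 hrde-1-dependent regions H3K9me3 had a median log2 change of -0.60 in morc-1 late, with 400 lower, 149 called down and 1 called up (camera unadjusted p = 7.66e-122, and 0.0162 with an estimated correlation). WT late is 1 library here, so these calls and p-values assume that it varies like the other groups. Among 10000 random sets matched on mean level the median ran from -0.048 to 0.036. In hrde-1 late it was -1.61, and hrde-1 stood below morc-1 by a further -0.96, with 299 regions called. The set was defined with WT late and hrde-1 late, so it is not independent of them. The 160 regions defined from the early libraries, most of them shared with the 412, gave -0.51 in morc-1 late (155 lower, 50 called). The authors' deposited table marks 215 regions as GRH, where the medians were -1.02 in morc-1 late (215 lower) and -1.61 in hrde-1 late, and 191 as GRTS, with -0.33 (13 called) and -0.92. How these classes were chosen is not given in the sources used here, so they were not taken as independent evidence. They shared 81 and 69 regions with the 412. The authors' deposited table lists lower H3K9me3 in morc-1 late at 270 and 339 regions in its 2 replicates, of which 125 and 151 lie among the 412.

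**Figure D3:**
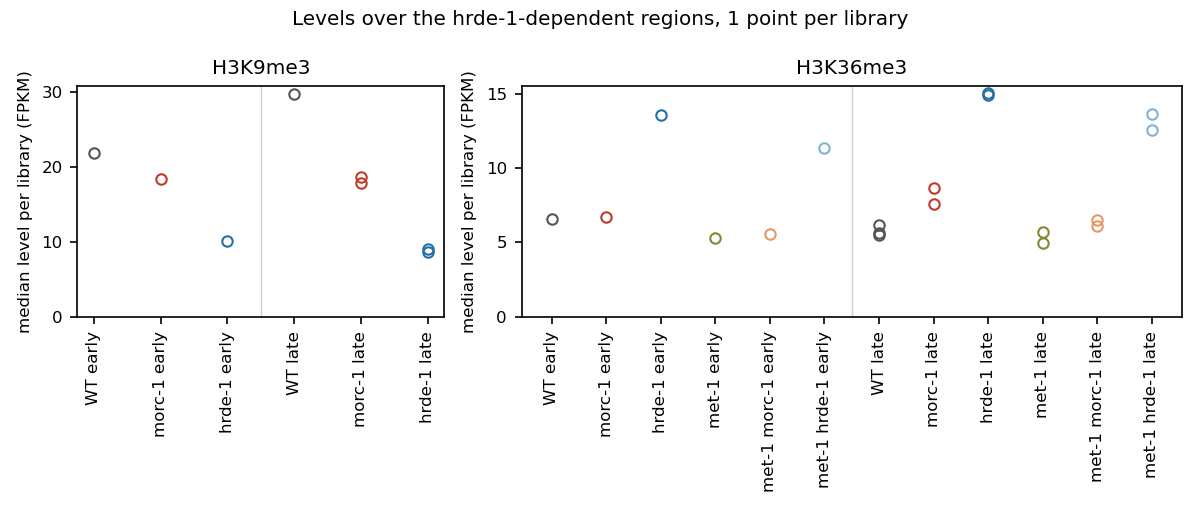
Median level (FPKM, y axis) over the 412 hrde-1-dependent regions in each library (points), by group (x axis) and mark. For H3K9me3 WT late stood at 29.8 FPKM, the morc-1 late libraries at 18.7 and 17.9, and the hrde-1 late libraries at 8.61 and 9.10.

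Early groups held 1 H3K9me3 library each, so no p was computed. Over the 412 regions the median log2 change against WT early was -1.07 in hrde-1 (391 lower) and -0.23 in morc-1 (345 lower), with no measure of the spread between libraries. Levels were 21.8 FPKM in WT early and 29.8 FPKM in WT late, a median change of 0.42 with 400 regions higher, a direction favoured because the regions were chosen for high WT late levels. Over the 160 regions defined from the early libraries it was 0.26 (136 higher), again from 1 library per stage. By their sample names WT early and WT late carry different replicate numbers, as do WT early and hrde-1 early. The change in WT, the early hrde-1 change and the choice of the 160 regions thus also cross replicate numbers, which cannot be told apart from stage or strain. In morc-1 the late libraries differed from the early library by 0.013 and in hrde-1 by -0.059. The interaction of generation and morc-1 had a median of -0.41 (camera unadjusted p = 0.0609 with an estimated correlation; -0.30 and 0.106 over the 160 regions) and 1 regional fall (unadjusted p below 0.05 for 237 higher and 1089 lower). That with hrde-1 had a median of -0.51 over the 412 regions, whose choice by the late hrde-1 fall favours this sign, and -0.24 over the 160 regions (camera unadjusted p = 0.177 with an estimated correlation; 0 called by limma), with 41 falls over all regions. Late against early, morc-1 had 1 fall and hrde-1 65, with 0 rises in either.

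H3K36me3, a mark of transcribed chromatin, rose over the same 412 regions, with a median log2 change of 1.15 in hrde-1 late (399 higher, 352 called up and 4 down) and 0.32 in morc-1 late (347 higher, 24.5% of the regions called up and 3 called down). Both passed camera with an estimated correlation (unadjusted p = 1.20e-04 and 0.00109). II 12741001 to 12749000 went from 7.87 ± 0.379 FPKM in WT late (SD, n = 3) to 17.5 ± 2.98 in morc-1 late and 27.9 ± 1.69 in hrde-1 late, whereas V 17638001 to 17651000 went from 8.19 ± 0.262 to 7.23 ± 0.332 and 25.9 ± 2.70 FPKM. I 4460001 to 4469000 held 6.60, 8.93 and 19.02 FPKM and I 2046001 to 2054000 held 12.5, 21.1 and 25.5 FPKM. Over all regions morc-1 late had 421 rises, 197 of them in the chromosome V block of raised morc-1 input, and 10 falls (634 and 93 with a library series block, 1002 and 1212 as ratio to input). The largest rises were at II 14986001 to 14987000 (3.82 ± 0.549 to 15.6 ± 2.36 FPKM, 1.78 ± 0.16, limma adjusted p = 2.18e-08), I 11681001 to 11682000 (6.01 to 21.7 FPKM), I 2058001 to 2059000 (5.64 to 20.8), V 15595001 to 15596000 (7.28 to 24.8) and IV 13638001 to 13639000 (4.54 to 16.21). Falls were at II 4258001 to 4259000 (-2.29 ± 0.19), II 4259001 to 4260000 (-1.99) and II 4257001 to 4258000 (-1.39), where WT input was also high, at V 2091001 to 2092000 (-1.02) and at III 2110001 to 2111000 (-0.87). hrde-1 late had 1921 rises and 11545 falls, with the median of all regions shifted by -0.278, and 872 and 428 after quantile normalization. The 13466 calls became 839 without hrde-1 late replicate 1, 23070 without replicate 2, 6573 without WT late replicate 2 and 2616 without WT late replicate 3, and the 431 morc-1 calls became 174 without morc-1 late replicate 2. Rises common to both mutants numbered 203 (8.07 by independent calls, covariance 0.0225 against 0.0154 simulated), and part of the excess may come from the shared controls. Simulation with shared WT late libraries and no mutant effect gave 0, but few calls arise there at all, so it does not measure that part. Regions with a fall of H3K9me3 and a rise of H3K36me3 numbered 693 in hrde-1 late (23.4 by independent calls) and 125 in morc-1 late (1.54).

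Early, with 1 library per group, the H3K36me3 medians over the 412 regions were 0.91 in hrde-1, 0.067 in morc-1 and -0.27 in met-1. The interactions of generation gave 0.30 for morc-1 (camera unadjusted p = 0.0928 with an estimated correlation; 0 regions called in either direction by limma, unadjusted p below 0.05 for 1288 higher and 706 lower) and 0.22 for hrde-1 (unadjusted p = 0.0308; 6 falls over all regions), and over the 160 regions 0.23 for hrde-1 (unadjusted p = 0.0599). Over GRH regions the late medians were 0.37 in morc-1, 0.71 in hrde-1 and -0.16 in met-1, and over GRTS regions 0.093 in morc-1 (14 called up; camera unadjusted p = 0.0795 with an estimated correlation), 0.99 in hrde-1 and -0.017 in met-1.

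To ask whether met-1 is needed for the mutant changes, the met-1 strains were compared late. met-1 alone had 57 rises and 2482 falls of H3K36me3 against WT (961 and 5408 with a library series block, 2090 and 5528 as ratio to input), with 900 falls among 17713 X-linked regions (5.08%). Over the 412 regions its median was -0.096 (276 lower, 51 called down), within the -0.181 to -0.056 of the random sets. Against met-1, met-1 morc-1 had 271 rises and 33 falls (827 and 1038 with a library series block, 815 and 1067 as ratio to input), with a median of 0.18 over the 412 regions (247 higher, 76 called up; camera unadjusted p = 0.0107 with an estimated correlation). The median was -0.111 over the regions with at least 40 FPKM in WT late, and -0.142 over GRTS regions, where random sets had a median of -0.148 and 9 regions were called up and 0 down by limma. met-1 hrde-1 had 708 rises and 99 falls (1270 and 1202 with a library series block, 1988 and 1819 as ratio to input), with a median of 1.08 (401 higher, 274 called up). For both double mutants the median of all regions was shifted by -0.149. The morc-1 effect in met-1 differed from that in WT by a median of -0.17 over the 412 regions (296 lower; below all random sets, -0.108 to 0.014; camera unadjusted p = 0.698 with an estimated correlation), by 0.051 over GRH regions and by 7 rises and 6 falls over all regions. The hrde-1 effect differed by 0.045 (random sets -0.082 to 0.100; camera unadjusted p = 0.553 with an estimated correlation) and by 22 rises and 14 falls. The double mutants also stood apart from their single mutants, with 913 rises and 5808 falls for met-1 morc-1 against morc-1 and 1009 and 5910 for met-1 hrde-1 against hrde-1. Without met-1 late replicate 1 the 2539 met-1 calls became 451, without met-1 late replicate 2 they became 1585 and without WT late replicate 2 they became 1454. The 304 met-1 morc-1 calls became 172 without met-1 morc-1 late replicate 1, 159 without replicate 2, 172 without met-1 late replicate 1 and 199 without met-1 late replicate 2.

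Input DNA differed between strains in blocks. On chromosome V from 2348001 to 2563000 (215 regions) the input stood at 2.99 and 2.95 times the level of the 100 kb on either side in morc-1 early and late, at 0.990 and 1.03 in WT, at 0.526 and 0.521 in hrde-1, at 0.513 and 0.524 in met-1 at 0.541 and 0.525 in met-1 hrde-1, and at 1.041 and 1.039 in met-1 morc-1. This block held 214 of the 225 H3K9me3 rises and 197 of the 421 H3K36me3 rises in morc-1 late, and 29 of the 271 H3K36me3 rises of met-1 morc-1 against met-1, where input differed by 0.892 on the log2 scale. With the 333 regions of unequal input left out, morc-1 late had 9 rises and 328 falls of H3K9me3 and 186 rises and 3 falls of H3K36me3. On chromosome II from 4257001 to 4260000 the WT input stood at 4.99 and 5.40 times the flanking level. Of the 1221 H3K9me3 falls in hrde-1 late, 1117 lay outside unequal input, and unequal input covered 4 of the 366 falls in morc-1 late and 4 of the 412 hrde-1-dependent regions. In hrde-1, input stood above WT by 0.789 on the log2 scale at IV 13859001 to 13915000, 0.917 at V 18703001 to 18725000 and 0.846 at III 333001 to 341000.

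**Figure D4:**
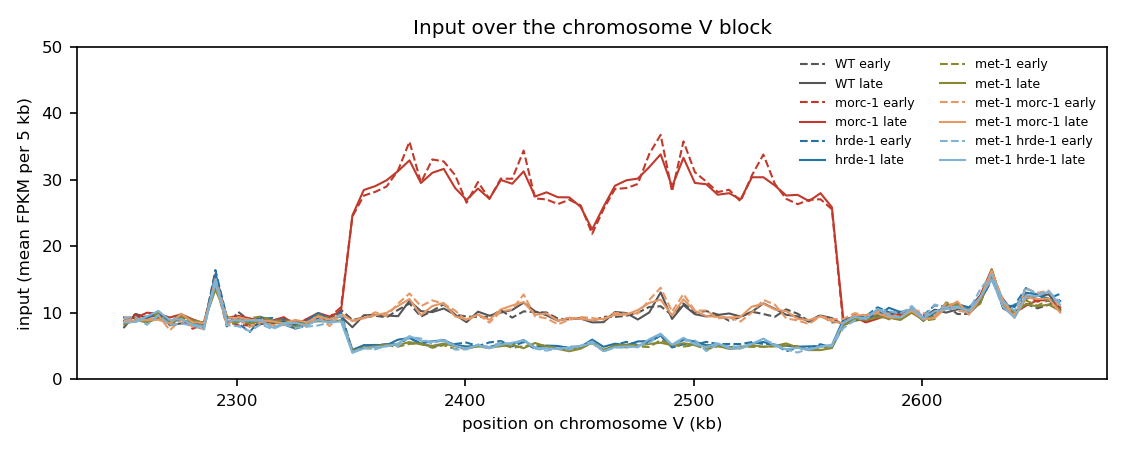
Input (mean FPKM per 5 kb, y axis) against position on chromosome V (kb, x axis) around the block from 2348001 to 2563000; each line is the input of a strain and stage. Inside the block the morc-1 inputs stood near 3 times their flanks (2.99 and 2.95) and the hrde-1 inputs near 0.526 and 0.521.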

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

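The permutations of libraries and the test of a single WT late library were chosen before the results they measure were seen, and the other tests after. In 3 RNA results a test of the difference between stages itself called genes or features. The interaction of generation and hrde-1 held 3 mRNA genes, 2 of them with a group listed at 0, and 478 small RNA features. The interaction of generation and morc-1 held 42 small RNA features. At the hrde-1-dependent regions the interaction of generation and hrde-1 was -0.507 for H3K9me3 and 0.221 for H3K36me3, but these regions were chosen for a late fall of H3K9me3 in hrde-1, which favours the sign of the first. At regions defined from the early libraries they were -0.236 and 0.233. Selection there was on early H3K9me3 and favours the other sign for H3K9me3 only. Neither passed camera with an estimated correlation, so a difference between stages is not shown there. Each regional interaction rests on 1 early library per group, and for H3K9me3 the WT early and hrde-1 early libraries carry different replicate numbers by sample name. Signals in input, which was used to filter regions and in the ratio to input, were 2.95 times the flanks in morc-1 late on chromosome V, 5.40 times in WT late on chromosome II, and 0.789 and 0.917 on the log2 scale above WT in hrde-1 on chromosomes IV and V.

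Strain labels of the small RNA libraries were also exchanged within each generation. Of 100 such arrangements, 9 gave at least as many interaction calls as the real 42, with up to 1231. An exchange in 1 generation only carries the strain effect itself into the interaction, so high counts can arise from that alone. They cannot decide whether the 42 calls reflect a difference between stages or other structure among libraries. For the group comparisons of 3 against 3 libraries only 10 splits exist, too few for a test: the real split gave 372 calls against at most 22 for morc-1 early, 1061 against 0 for morc-1 late, 12 against 0 for WT late against early, and 246 against 0 for morc-1 late against early, with 1 of 10 splits reaching the real value in each case.

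H3K9me3 and H3K36me3 both rose in morc-1 late over the chromosome V block. The input rose with them, by a median of 1.48 on the log2 scale late and 1.482 early, so a wrongly labelled late input is argued against. H3K9me3 divided by input differed by 0.0114 with a spread of 0.2502 (SD), which argues against a change of the mark itself. A higher DNA copy number of the block in this morc-1 strain could give the 1.48. In met-1 morc-1 the late input stood at 1.039 times the flanks, so a gain over the flanks was not seen in both morc-1 strains. Against met-1, however, the late input of met-1 morc-1 was higher by a median of 0.892 on the log2 scale. The lower input of hrde-1 and met-1 strains (0.521 and 0.524 times the flanks) may reflect strain background. Which allele of the block the strains carry was not tested.

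In WT, germline lists were lower and somatic lists higher late than early, by a median difference of 1.801 on the log2 scale. After quantile normalization it was 1.44 (SD 0.498), without WT late replicate 2 it was 1.52 (SD 0.567) and without replicate 1 it was 2.08. In single libraries somatic minus germline stood at 0.887 and 1.45 in WT late against -0.948 and -0.322 in WT early. Quantile normalized, it stood at 0.743 and 0.992 against -0.867 and -0.283. The 1.44 and 1.52 fell short of the multiple of their SD set for arguing against the deposited scaling or a single library. These tests therefore cannot decide, although both WT late libraries stood above both WT early libraries in either scaling. Whether all or part of the difference came from either is open. A lower share of germline tissue in the animals collected might move all 4 somatic lists alike; their changes ranged over 0.942 with a spread of 0.915, which does not decide. Collection at a different age or fertility at 25 °C remains open, as no separate measure of tissue share was available.

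H3K9me3 was lower in morc-1 late at hrde-1-dependent regions (-0.598). Selection of the regions on the shared WT late library is argued against by -0.513 at regions defined from the early libraries, and unequal input by -0.595 without regions of unequal input. Random sets reached no lower than -0.0484. They were matched on the mean of all libraries, those of hrde-1 included, and not on the WT level. They therefore cannot exclude a weaker immunoprecipitation in morc-1. A WT late library that stands apart from others of its kind stays open, because WT late is 1 library; in the early libraries, also 1 per group, morc-1 was lower by 0.231. A partial need for morc-1 at these regions is thus a hypothesis beside the causes left open here, and more WT late libraries would be needed to test it.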

How the results depend on the processing

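Direction held for most named genes and lists, and less often for H3K36me3. For mRNA 2865 such values stayed, 342 weakened, 4 strengthened and 20 reversed, and for small RNA 1780 stayed, 159 weakened and 2 reversed. Stayed means the same side of the threshold and the same direction. A value not called in the main fit also counted as stayed where its sign changed. For the H3K36me3 differences between met-1 and WT backgrounds 25 stayed, 8 strengthened, 7 weakened and 6 reversed, and 2 other H3K36me3 medians reversed and 2 weakened. RNA counts moved more: 93 mRNA counts stayed within 1.5 times their value and 68 did not, against 134 and 60 for small RNA. For chromatin the tally holds counts and region medians, with 51 stayed and 5 moved for H3K9me3 and 133 and 24 for H3K36me3. Late medians in it were not held to 1.5 times: that of H3K9me3 in morc-1 over GRH regions, -1.02 against -0.598, counted as stayed. The chromatin tallies therefore cannot be compared with the RNA counts. The median H3K9me3 change in morc-1 late at hrde-1-dependent regions kept its sign in the alternatives run, and its size with each morc-1 late or hrde-1 late library left out (-0.640 to -0.559; WT late, a lone library, was never left out) but not with other regions (-0.928 with a log2 drop of at least 2, -0.36 with at least 40 FPKM in WT late, -1.02 over GRH and -0.335 over GRTS regions). Where fewer libraries or more genes entered the fit, that change is part of the setting; otherwise the cause was not tested. Depth limits small RNA in morc-1 early replicate 1 most, and mRNA depth is unknown. Not run were the overlap of genes with regions, since no annotation of the files' build was available, and the F5 experiment.

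For mRNA calls, a pseudocount of 5 gave 6 for the interaction of generation and hrde-1. Without a filter on low values there were 15 for morc-1 early, 120 for hrde-1 early, 1536 for hrde-1 late, 315 for WT late against early, 85 for morc-1 and 195 for hrde-1 late against early, 1 for the interaction with morc-1 and 24 for that with hrde-1. Quantile normalization gave 41 for morc-1 late, 799 for WT, 45 for morc-1 and 334 for hrde-1 late against early. With only the compared groups in the fit there were 2 for morc-1 early, 5 for morc-1 late, 80 for hrde-1 late, 52 for WT and 40 for hrde-1 late against early, 6 for the interaction with hrde-1 and 5 for the late overlap of both mutants.

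The replicate number as a block gave 15 mRNA calls for morc-1 late and 15 for the overlap. A block within each generation, chosen after seeing the data, gave 18 for morc-1 early, 1121 for morc-1 late (200 of them falls, against 0), 78 for hrde-1 early, 710 for hrde-1 late, 4413 for WT, 1053 for morc-1 and 3574 for hrde-1 late against early, 620 and 8 for the interactions with morc-1 and hrde-1, and 250 for the overlap. Libraries of the same number correlated at r = 0.429 to 0.554 within a generation (12 pairs) and -0.222 to 0.0469 across generations (18 pairs); in groups of 2 both numbers give the same r, and the labels do not say what a number shares, so pairing within a generation stays open. Late against early, such a block does not cancel, so those counts may be too high (4413, 1053 and 3574). For small RNA the replicate block gave 525 calls for morc-1 late, 24 for WT and 89 for morc-1 late against early, 24 for the interaction with morc-1 and 422 for the overlap. For H3K36me3 the replicate block gave 495 for met-1 morc-1 against met-1, and a difference of hrde-1 effects of -0.00260, reversed. A library series block gave 727 for morc-1, 6369 for met-1, 1865 for met-1 morc-1, 2472 for met-1 hrde-1, and a difference of hrde-1 effects of -0.0118, reversed.

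Leaving out genes with a 0, chosen after seeing the data, gave 12 mRNA calls for morc-1 late against early and 1 for the interaction with hrde-1, and reversed the yolk list late against early in morc-1 (0.159) and hrde-1 (1.04), as signed -log10 camera p. Leaving out the late libraries numbered 2, also chosen afterwards, gave 5 for morc-1 early, 2 for morc-1 late, 23 for hrde-1 late against early, 1 and 6 for the interactions, and 2 for the overlap. It reversed collagens (-0.0822) late against early in WT, muscle (-0.217) and collagens (-1.50) in hrde-1, and major sperm proteins (3.27) in the interaction with morc-1.

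For small RNA, quantile normalization gave 707 calls for morc-1 early, 28 for WT and 492 for hrde-1 late against early, 249 for the interaction with hrde-1 and 2 lists, and reversed hpl-1 (0.0398) and cec-4 (0.275) in hrde-1 late. With only the compared groups there were 185 for morc-1 early, 1 for WT, 74 for morc-1 and 1540 for hrde-1 late against early, 13 for the interaction with morc-1 and 2 lists. edgeR gave 34 for WT late against early and 82 for the interaction with morc-1, and DESeq2 gave 58, 131 and, for morc-1 late against early, 397. Leaving out the shallowest library, chosen afterwards, gave 24 for WT late against early and 17 for the interaction with morc-1, and taking identical features once gave 1 list.

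For chromatin, the ratio to input gave 1003 H3K9me3 calls for morc-1 and, for H3K36me3, 28176 for hrde-1, 2214 for morc-1, 7618 for met-1, 1882 for met-1 morc-1 and 3807 for met-1 hrde-1. Without regions of unequal input, chosen afterwards, morc-1 had 337 H3K9me3 and 189 H3K36me3 calls, and quantile normalization gave 1300 H3K36me3 calls for hrde-1. The early H3K9me3 median of morc-1 was -0.325 over regions with a log2 drop of at least 2 and -0.421 over GRH regions. With at least 40 FPKM in WT late, the H3K36me3 medians were -0.0451 for met-1 (weaker), -0.111 for met-1 morc-1 against met-1 (reversed) and -0.0742 for the difference of hrde-1 effects (reversed). Over GRTS regions, chosen afterwards, they were -0.0170 for met-1 (weaker) and -0.142 for met-1 morc-1 (reversed, although matched random sets had a median of -0.148).

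With each library of the compared groups left out in turn, where a lone library is assumed to vary like the other groups, mRNA calls ranged from 5 to 9 for morc-1 early, 7 to 15 for morc-1 late, 115 to 270 for hrde-1 late, 28 to 1053 for WT, 12 to 14 for morc-1 and 22 to 2062 for hrde-1 late against early, 0 to 1 and 1 to 26 for the interactions and 6 to 25 for the overlap. Small RNA calls ranged from 701 to 1038 for morc-1 late, 808 to 1271 for hrde-1 early, 3 to 24 for WT, 136 to 390 for morc-1 and 322 to 358 for hrde-1 late against early, 11 to 84 for the interaction with morc-1, 2 to 4 lists, 518 to 809 for the overlap and about 1.0e+02 to 481 for the interaction with hrde-1. H3K9me3 calls for hrde-1 ranged from 834 to 1079. H3K36me3 calls ranged from 839 to 23070 for hrde-1, 174 to 393 for morc-1, 451 to 1830 for met-1 and 159 to 199 for met-1 morc-1. The difference of hrde-1 effects reversed without WT late replicate 3 (-0.00260), met-1 late replicate 1 (-0.0260) and met-1 hrde-1 late replicate 2 (-0.0138), and was at most 0.113. As signed -log10 camera p, the lists that reversed ranged as follows: oogenesis from -13.2 to 1.85 in hrde-1 early (without WT early replicate 2 and 1) and -0.160 to 6.42 in hrde-1 late (without WT late replicate 1 and 2). Between leaving out WT late replicate 1 and 2, collagens ranged from -7.17 to 1.12 in morc-1 late, 6.97 to -0.101 in WT late against early and -5.79 to 0.371 in the interaction with morc-1, and major sperm proteins from -14.4 to 2.93 in that interaction. Collagens in morc-1 late also reversed without morc-1 late replicate 1 (0.0257). Intestine ranged from -0.190 to 4.25 in morc-1 early (without morc-1 early replicate 1 and 2). Between leaving out hrde-1 late replicate 1 and 2, histones ranged from 0.254 to -9.48 and muscle from 0.150 to -11.7 in hrde-1 late, histones from 0.646 to -8.93 and muscle from 0.289 to -12.8 in the interaction with hrde-1, and muscle from 7.09 to -0.236 and collagens from 7.23 to -1.38 in hrde-1 late against early.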

Other observations

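These values were singled out after the data were seen. F58H7.5 and C38D9.2 rose in mRNA and in small RNA in morc-1 late (small RNA log2 0.82 and 0.64), whereas rnh-1.3 fell in small RNA by 4.05. The small RNAs of trp-4 were nearly lost in hrde-1 late (8.15 ± 1.55 normalised reads, SD, n = 2) but stood at 1763 ± 322 in morc-1 late against 1902 ± 515 in WT late (n = 3). eri-6, an ERI pathway helicase gene, held more small RNAs in morc-1 late (15840 ± 2425 reads) than in WT late (9271 ± 581) and few in hrde-1 late (769 ± 27.7). his-24, a linker histone gene, moved in opposite directions, up by 1.03 in morc-1 late and down in hrde-1 late (-3.16).

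Measured by the authors' classes, the median H3K9me3 change over 215 GRH and 191 GRTS regions was -1.02 and -0.33 in morc-1 late and -1.61 and -0.92 in hrde-1 late, and the difference between classes was not tested. Among long runs, II 12741001 to 12749000 held 6 GRH regions and I 4460001 to 4469000 held 8, while V 17638001 to 17651000 held 0.

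In the main fit the genes of the nuclear RNAi machinery (7 measured, morc-1 and hrde-1 among them) did not pass in any late mutant comparison. With a replicate block within each generation, morc-1 itself passed in morc-1 late. The list medians in the main fit were 0.50 in morc-1 late and 0.090 in hrde-1 late. The PRC2 and MES factors (4 measured) also did not pass, with medians of 0.74 and 0.34. C33B4.4 stood at 20.1 ± 0.511 FPKM in WT late, 12.5 ± 0.121 in morc-1 late and 8.33 ± 1.82 in hrde-1 late.

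In single mRNA libraries the somatic minus germline level was 0.887 and 1.45 on the log2 scale in WT late, -0.535 and 1.07 in hrde-1 late, and -0.323 and 0.2498 in morc-1 late. Replicate 2 thus stood above replicate 1 within each late group, and morc-1 late stood below WT late at either number. Along the first principal component (43.7% of the variance) the WT late libraries stood at 29.8 and 59.8.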
